A study of Homo sapiens with 15 samples.

How the data were processed

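RNA levels were measured on 15 Affymetrix U133 Plus 2.0 arrays, which read human transcripts with 54675 probe sets. Per the labels, the RNA came from cultures of U251, an established human glioma line, in 5 groups of 3 biological replicates. Cells were grown for 1 day and, in 4 of the groups, given the iron chelator deferoxamine (DFO, 300 µM for 16 h), which stabilises hypoxia-inducible factors in air. The DFO cells received no further agent, a small interfering RNA (siRNA) against HIF1A for 48 h, a DNA-binding polyamide directed at the hypoxia response element (1 µM for 48 h), or the DNA-binding antibiotic echinomycin (100 nM, added 2 h before DFO). A group given a control siRNA was not among them. Groups were taken from the sample titles. The description field of the labels names another line, LNCaP, with androgen treatments, while titles, source names and protocols name U251 and DFO, so markers of both kinds of cell were checked. Replicate numbers of the cells without DFO were also taken from the titles, since the source names number them differently.

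The deposited values are intensity, the signal per probe set from the Affymetrix software GCOS, per the submitters' processing notes. Its version, scaling target and detection calls are not given in the sources used here. The values were positive on a linear scale from 0.0191 to 12578. No 2 arrays held identical values. The trimmed means of the arrays, leaving out 2% at each end, ran from 44.3 to 108, and the array medians spread over 1.23 log2 units. Because that spread was above the limit of 0.3, log2 signal was centred on each array's median instead of keeping the deposited scale. Group levels below are given as mean ± SD of the centred signal over 3 arrays.

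Gene symbols came from the platform annotation, updated by Entrez identifier. Exactly 1 symbol was given for 41097 probe sets, several for 1801 and none for 11777. Of the probe sets with 1 symbol, 41043 matched the current table, 54 kept the annotated symbol, and 0 symbols changed in the update. They covered 19775 genes. Each gene was read from its probe set with the highest mean, and genes under the 40th percentile of all probe sets (a signal of 8.76) were left out, which left 14320 genes.

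Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, both directions). All 15 arrays entered 1 fit with 1 mean per group and 10 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, called under 0.05, and errors after a log2 fold change are standard errors from limma. The 4 comparisons of the series design were DFO against no DFO and each treatment against DFO alone. The other 3 compared the treatments with each other. A gene counted as induced when DFO raised it at least 4-fold, and as lowered by a treatment when it was at least 2-fold below DFO alone, both with a call. The number of arrays limits the precision. In data simulated for polyamide against DFO over 14320 genes, with 200 genes changed, the fit recovered 53% of 2-fold and 84% of 4-fold changes, and 5.52% of its calls were false. The simulated noise was independent between genes, and the real comparison had 2379 calls, so these shares need not hold in the data.

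The 20 gene lists were tested with camera (limma, preset correlation 0.01), adjusted over the 80 tests of the design's comparisons and, separately, over the 60 tests of the direct comparisons. Camera with an estimated correlation and fry were alternatives. The lists named 530 genes, of which 487 were on the array with 1 symbol and 436 passed the filter. Some genes stand in several lists, such as SLC2A3, ALDOC, PDK1 and PFKFB4 among both HIF targets and glycolysis, so these calls share genes. The glycolysis list also holds the glycogen genes GYS1 and GBE1 and the kinase PDK1. A further 5 lists held cell type markers. The genes named below follow a rule. Per comparison of the design, these were the 10 largest rises and falls among called genes whose arrays did not overlap between groups and whose higher group reached the median of all probe sets (a signal of 13.3). For each direct comparison 5 were taken. By chance, 10% of genes have groups of 3 that do not overlap. Up to 4 list members with the smallest adjusted p and a few genes of hypoxia and iron biology were added. The design, lists, alternatives and naming rule were fixed before the data were examined.

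Alternatives covered quantile normalization, centring on the tested genes, an offset or a floor before log2, other filters, all probe sets, another choice of probe set per gene, other variance models, array weights, only the groups compared, a replicate block, other thresholds, and leaving out each array. Added after seeing the data were the deposited scale without centring, scaling to 9 hybridization spike-in probe sets, the ratio of 5' to 3' ACTB signal as a covariate, and leaving out 3 doubted arrays together. Correlations and overlaps between comparisons that share the DFO arrays were set beside 50 simulated unchanged groups. Genomic spans of genes came from the RefSeq table of GRCh38.p14, which covered 99.9% of the tested genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots. One of the genes the rule always names and some list members are not reported here.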

Results

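RNA from U251 glioma cells was read on 15 arrays, 3 per group: cells without DFO (no DFO), cells given DFO alone, and DFO-treated cells that also received HIF1A siRNA, the polyamide or echinomycin. The series asks how these agents change transcription driven by hypoxia-inducible factors, which DFO stabilises by removing the iron their degradation needs. The median deposited signal per array ran from 10.6 to 24.9, and array 3 of the cells without DFO was the highest. On the deposited scale, 11.5% to 13.0% of probe sets were above a signal of 100 on the echinomycin arrays, against 19.0% to 24.8% on the other arrays; after median centring the shares were 14.74% to 15.55% against 16.87% to 21.95%. Replicates correlated across the 14320 tested genes with r between 0.934 and 0.965. The 12 glioma and astrocyte markers had a median percentile of 94.0 among genes, with VIM at 99.9 and CD44 at 99.6 but S100B at 10.8, AQP4 at 13.1 and CHI3L1 at 19.3. The 10 markers of LNCaP prostate cells, the line in the conflicting label field, had 35.2, and KLK3 (prostate-specific antigen) had mean signals of 71.7 to 79.0 in the 5 groups. The 8 epithelial markers had a median percentile of 26.7, with KRT18 at 96.7 and KRT8 at 87.2, the 6 leukocyte markers 26.9 and the 6 endothelial markers 15.7. Signals of different probe sets are not on one scale, so these ranks are a rough guide.

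HIF1A, the target of the siRNA, fell in all 3 siRNA arrays. Its signal was 399, 387 and 536 there, against 2921, 3222 and 3275 with DFO alone (log2 fold change −2.85 ± 0.19, n = 3 per group, adjusted p = 2.19e-09). It was 4247, 4285 and 2496 without DFO, 2835, 3548 and 2941 with the polyamide, and 2766, 2330 and 2569 with echinomycin. DFO did not move HIF1A RNA past the threshold (−0.19 ± 0.19, adjusted p = 0.606), though without array 3 of the cells without DFO the value was −0.44 (adjusted p = 0.0253) and after quantile normalization −0.28 (adjusted p = 0.0442). The polyamide value was −0.02 (adjusted p = 0.964). With echinomycin it was −0.30 (adjusted p = 0.2), quantile normalization made it −0.77 (adjusted p = 2.51e-06), and centring on the tested genes turned it to 0.70 (adjusted p = 4.37e-05). The plot of signal per array shows HIF1A beside 5 genes of the response to hypoxia.

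**Figure D1:**
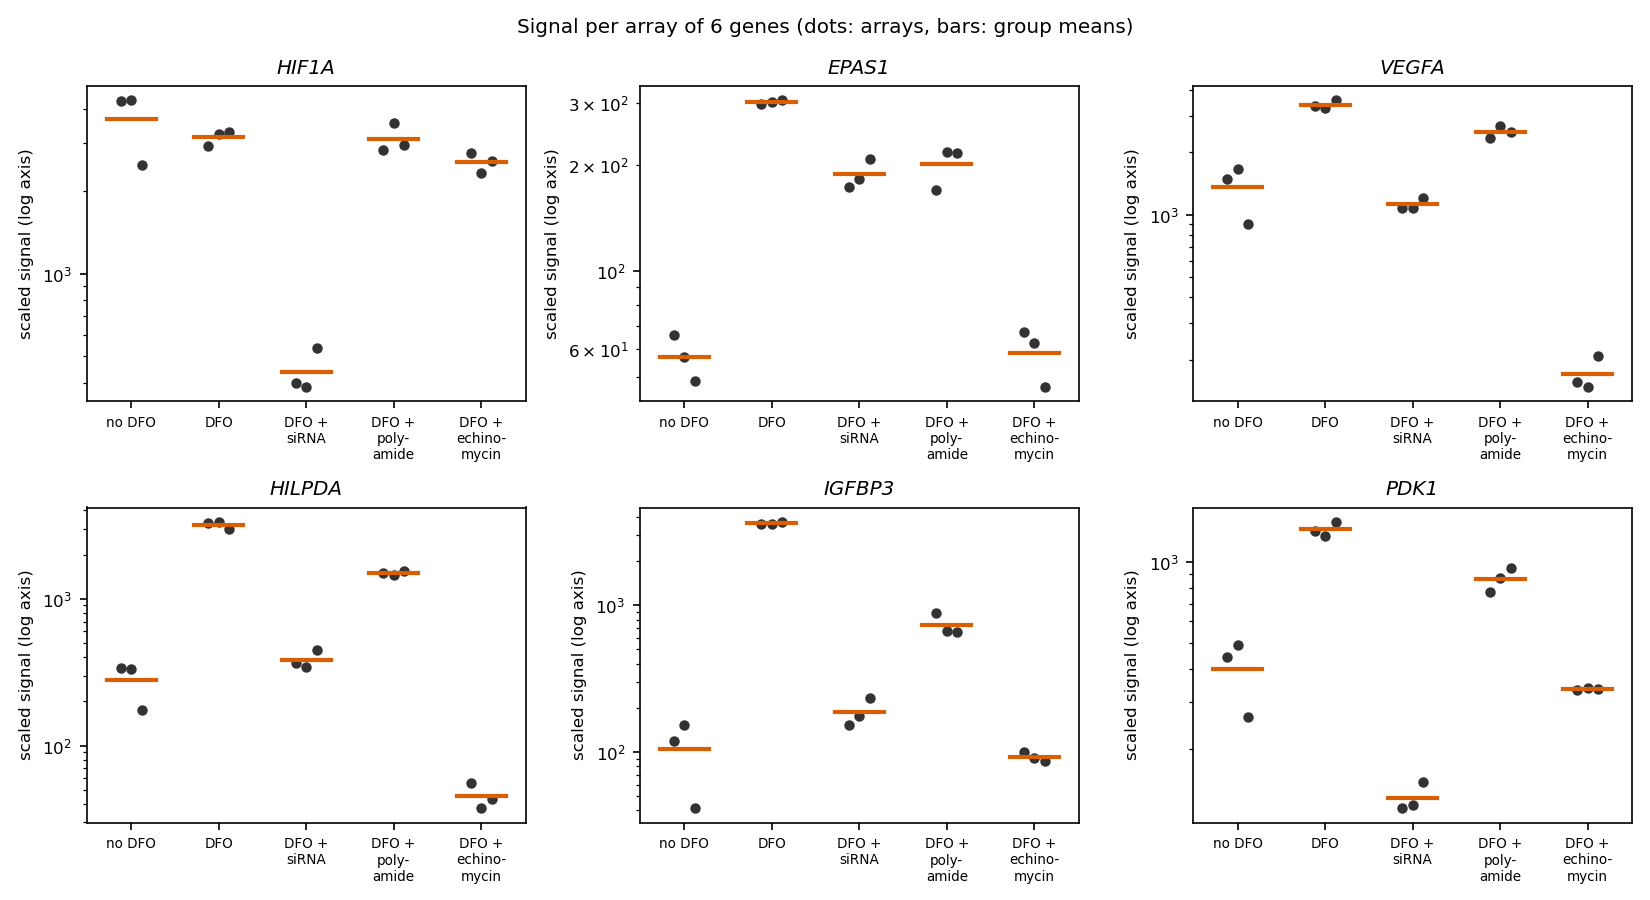
Scaled signal (log axis) of HIF1A, EPAS1, VEGFA, HILPDA, IGFBP3 and PDK1 in the 5 groups; dots are arrays (3 per group) and bars are group means. HIF1A was between 387 and 536 in the siRNA arrays, below every other array.

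DFO against no DFO asked what the hypoxia mimetic does to U251 RNA. DFO raised many genes of the response to low oxygen. IGFBP3, a carrier of insulin-like growth factors, rose from 104 ± 57.2 to 3616 ± 78.1 (5.32 ± 0.30, n = 3 per group, adjusted p = 2.41e-10). HILPDA, which coats lipid droplets, rose from 281 to 3197 (3.57 ± 0.21), and LOX, which crosslinks collagen, from 310.0 to 2648 (3.15 ± 0.19). VEGFA, the main angiogenic factor, rose from 1353 ± 398 to 3374 ± 157 (1.36 ± 0.19, adjusted p = 2.72e-05). EPAS1, which encodes HIF-2α, rose from 57.2 to 301 (2.41 ± 0.18, adjusted p = 1.12e-08). TFRC, the transferrin receptor that iron shortage stabilises, rose from 3418 to 5801 (0.80 ± 0.18, adjusted p = 0.00371; 0.0565 with only the groups compared in the fit). The cell cycle regulators CDC20 and CCNB1 fell, CDC20 from 1329 to 166 (−2.96 ± 0.19) and CCNB1 from 2047 to 388 (−2.37 ± 0.17).

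In all, 1319 genes rose and 752 fell of the 14320 tested, 688 and 229 of them at least 2-fold. Among the largest rises were ANGPTL4, a lipase inhibitor (5.95 ± 0.77, from a dim 5.81 to 168), the nuclear receptor RORA (4.10 ± 0.34) and the stress and growth response factors FOS (4.26), EGR1 (4.10), ATF3 (4.07) and MAFF (3.92). MAP7D2 (4.37), the protease MMP10 (4.14) and the retinoic acid hydroxylase CYP26A1 (3.79) rose from dim levels too. The largest falls included the mitotic kinase PLK1 (−2.42), the mitotic motor KIF20A (−2.53), the cyclin CCNF (−2.67) and RRP9, which serves ribosomal RNA processing (−2.71). KIF7 (−3.00) lost its call without array 1 or 2 of the cells without DFO (adjusted p = 0.0747 and 0.0726). FLT1 (0.42, adjusted p = 0.457), EDN2 (1.55, adjusted p = 0.124) and ARNT (0.19, adjusted p = 0.687) did not pass.

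Among HIF targets, 33 of 36 rose and 3 did not pass (35 rose when adjusted over the list alone; median 1.84; camera adjusted p = 1.03e-32, adjusted p = 0.129 with an estimated correlation). KISS1R (3.73) and the MYC antagonist MXI1 (2.48) were among them. Glycolysis genes rose in 16 of 24 (19 adjusted over the list alone), with the glucose transporter SLC2A3 at 2.16, ENO2 at 2.04 and the glycogen synthase GYS1 at 2.03 (adjusted p = 8.77e-14; adjusted p = 0.24 with an estimated correlation). Of 24 prolyl, lysyl and histone hydroxylases, iron enzymes that use oxygen, 16 rose (17 adjusted over the list alone), among them P4HA2 (2.10), KDM3A (2.08) and EGLN1 (1.63). Their camera adjusted p was 2.71e-12 (adjusted p = 0.163 with an estimated correlation). Angiogenic and vasoactive factors rose in 6 of 17 (11 adjusted over the list alone), with interleukin-8 (CXCL8) at 3.25 and ADM at 1.93 (adjusted p = 1.58e-05; adjusted p = 0.24 with an estimated correlation). Of 29 extracellular matrix genes, 11 rose (11 adjusted over the list alone), such as COL4A1 at 1.53 (adjusted p = 5.15e-04; adjusted p = 0.554 with an estimated correlation). All 7 metallothioneins, metal-binding proteins, rose (7 adjusted over the list alone), MT3 most at 1.96 (adjusted p = 9e-06; adjusted p = 0.157 with an estimated correlation).

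Several stress lists rose with DFO as well, though heat shock proteins fell. Immediate early genes rose in 18 of 30 and fell in 2 (18 and 3 adjusted over the list alone), with the phosphatase DUSP1 at 3.46 and IER3 at 2.12 (adjusted p = 2.71e-12; adjusted p = 0.163 with an estimated correlation). The unfolded protein and integrated stress response rose in 15 of 25 (16 rose and 1 fell adjusted over the list alone), with PPP1R15A at 2.14 and CTH at 1.87 (adjusted p = 2.74e-10; adjusted p = 0.236 with an estimated correlation). NF-kB and inflammatory genes rose in 9 of 17 (12 adjusted over the list alone), with PTGS2 (cyclooxygenase-2) at 3.44 and TNFAIP3 at 2.96 (adjusted p = 6.61e-08; adjusted p = 0.101 with an estimated correlation). Of 19 p53 targets, 11 rose (11 rose and 2 fell adjusted over the list alone), with GADD45A at 2.30 and GDF15 at 1.98 (adjusted p = 4.53e-04; adjusted p = 0.383 with an estimated correlation).

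Proliferation genes and heat shock proteins went the other way. Mitosis genes fell in 30 of 33 (31 adjusted over the list alone; median −1.27; adjusted p = 6.02e-32, adjusted p = 0.129 with an estimated correlation), DLGAP5 among them at −2.25. Replication genes fell in 13 of 35 (2 rose and 13 fell adjusted over the list alone), with the helicase subunits MCM6 at −1.96 and MCM3 at −1.12 (adjusted p = 7.32e-06; adjusted p = 0.454 with an estimated correlation). Heat shock proteins fell in 6 of 11 (6 adjusted over the list alone), HSPE1 at −1.37 and HSPB1 at −0.75 among them (adjusted p = 1.33e-05; adjusted p = 0.392 with an estimated correlation). Oxidative phosphorylation had 1 higher and 2 lower of 37 (1 and 2 adjusted over the list alone), ATP5MC1 at −1.08, and its camera call (adjusted p = 0.0259; adjusted p = 0.821 with an estimated correlation) was lost without array 1 (adjusted p = 0.931) or 2 (adjusted p = 0.42) of the cells without DFO. Iron genes had 3 of 12 higher (3 adjusted over the list alone), TFRC, HMOX1 (0.85) and SLC25A37 (1.01), with no camera call (adjusted p = 0.23). Among cholesterol genes STARD4 (1.18) and INSIG1 (1.16) were higher, but the list had no call (adjusted p = 0.475; 3 rose and 1 fell, 3 and 3 adjusted over the list alone) and its balance turned under every other scaling. Interferon genes had 2 of 22 higher (1 adjusted over the list alone), with a median of −0.04, a mean of 0.02 and no call (adjusted p = 0.791), and their balance turned on the deposited and spike-in scales. The list of HIF subunits, which also counts VHL, not itself a subunit, had 1 of 6 higher (1 adjusted over the list alone), EPAS1 (adjusted p = 0.419). RNA polymerase II and general factors had 2 of 30 higher and 2 lower (4 and 6 adjusted over the list alone; adjusted p = 0.241). limma called 0 of 33 ribosomal protein genes, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.229). Across the 4 comparisons of the design camera called 46 of 80 tests with the preset correlation and 0 of those with an estimated one.

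The share of DFO calls that were lower was 36.3% with median centring, 54.0% after quantile normalization, 54.3% centred on the tested genes, 67.6% on the deposited scale and 74.3% scaled to spike-ins. Without array 3 of the cells without DFO, 3121 genes passed in place of 2071.

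HIF1A siRNA against DFO asked which DFO responses need HIF-1α. The siRNA lowered many of the hypoxia genes. PDK1, the kinase that inhibits pyruvate dehydrogenase, fell from 1329 ± 80.2 to 132 ± 16.9 (−3.34 ± 0.19, n = 3 per group, adjusted p = 3.54e-10). IGFBP3 fell from 3616 to 188 (−4.29 ± 0.30, adjusted p = 3.37e-09), LOX from 2648 to 321 (−3.05 ± 0.19), TMEM45A from 3126 to 398 (−2.98 ± 0.19), and VEGFA from 3374 to 1125 (−1.59 ± 0.19, adjusted p = 2.78e-06). Interferon genes rose instead, with IFI27 from 37.0 to 376 (3.33 ± 0.28) and ISG15, a ubiquitin-like antiviral protein, from 343 to 1144 (1.72 ± 0.18). EPAS1 fell from 301 to 188 (−0.69 ± 0.18, adjusted p = 0.00785).

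The siRNA raised 2624 genes and lowered 1226, of which 867 and 633 changed at least 2-fold. The largest falls were CFAP96 (−6.02 ± 0.54, 137 to a dim 2.35), the synaptic liprin PPFIA4 (−4.53), RORA (−4.49, 219 to 10.4), SEMA5B (−4.14), EFCAB3 (−3.95), ANGPTL4 (−3.93), PGM5 (−3.81), BEND5 (−3.75) and the aldolase ALDOC (−3.70, 254 to 22.1). Among the largest rises were LRP3 (3.98), the antiviral RSAD2 (3.76, from a dim 4.32 to 56.5), the collagenase MMP1 (3.76) and the potassium channel KCNQ5 (3.00). KIF7 and RRP9, lowered by DFO, rose here (both 3.30). EDN2, a vasoconstrictor peptide, fell (−2.94 ± 0.65, adjusted p = 0.00178). FLT1 fell (−1.14, adjusted p = 0.0111) but not without DFO array 3 (adjusted p = 0.0598) or siRNA array 1 (adjusted p = 0.0655). ARNT was −0.70 (adjusted p = 0.0304) and lost its call without DFO array 1 (0.0688) or 3 (0.196) or siRNA array 1 (0.14) or 2 (0.0943). TFRC was −0.20 (adjusted p = 0.486), and −0.32 after quantile normalization (adjusted p = 2.37e-04).

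HIF targets fell in 34 of 36, and 2 did not pass (36 fell adjusted over the list alone; median −1.98; adjusted p = 4.51e-36, adjusted p = 0.129 with an estimated correlation). Glycolysis genes fell in 18 of 24 and 1 rose (19 and 1 adjusted over the list alone), with PFKFB4 at −2.72, GYS1 at −2.27 and the glycogen brancher GBE1 at −2.27 (adjusted p = 1.44e-16; adjusted p = 0.191 with an estimated correlation). Hydroxylases fell in 15 of 24 (17 adjusted over the list alone), P4HA1 at −2.42 and KDM4B at −2.33 among them (adjusted p = 8.58e-13; adjusted p = 0.163 with an estimated correlation). All 7 metallothioneins fell (7 adjusted over the list alone), MT3 to −2.13 (adjusted p = 1.54e-06; adjusted p = 0.129 with an estimated correlation). Angiogenic factors fell in 8 of 17 and rose in 2 (11 and 3 adjusted over the list alone): ADM was lower (−1.76), while CXCL8 (1.87) and the receptor NRP1 (1.90) were higher (adjusted p = 0.00244; adjusted p = 0.413 with an estimated correlation). Immediate early genes fell in 11 of 30 and rose in 7 (12 and 7 adjusted over the list alone), with EGR1 at −2.77 and IER3 at −2.35, and lost the camera call (adjusted p = 0.00916; adjusted p = 0.61 with an estimated correlation) without siRNA array 3 (adjusted p = 0.0532).

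Interferon genes rose in 17 of 22 (18 adjusted over the list alone; median 1.16; adjusted p = 3.67e-09, adjusted p = 0.129 with an estimated correlation), with IFIT3 at 2.34 and IFI44L at 1.92. Replication genes rose in 20 of 35 (22 adjusted over the list alone), MCM6 at 1.51 and the clamp loader RFC4 at 1.08 (adjusted p = 2.66e-05; adjusted p = 0.49 with an estimated correlation). Mitosis genes rose in 12 of 33 and 1 fell (17 and 1 adjusted over the list alone), the kinase AURKB at 1.27 and CDC20 at 1.14 (adjusted p = 0.00383; adjusted p = 0.73 with an estimated correlation). Oxidative phosphorylation rose in 11 of 37 (12 adjusted over the list alone), ATP5MC1 at 1.48 and CYC1 at 0.96 (adjusted p = 0.00188; adjusted p = 0.74 with an estimated correlation). Heat shock proteins rose in 8 of 11 (8 rose and 1 fell adjusted over the list alone), HSPE1 from 927 to 3501 (adjusted p = 0.003; adjusted p = 0.547 with an estimated correlation). Matrix genes had 3 higher and 8 lower of 29 (3 and 9 adjusted over the list alone), with CCN2 at 2.08 and THBS2 at 2.07, and their call (adjusted p = 0.0235; adjusted p = 0.74 with an estimated correlation) was lost without siRNA array 1 (0.0898), 2 (0.14) or 3 (0.0777). Stress response genes had 3 higher and 9 lower of 25 (5 and 9 adjusted over the list alone), with ATF3 at −1.58 and DDIT4 at −1.25, and their call (adjusted p = 0.0343; adjusted p = 0.718 with an estimated correlation) was lost without siRNA array 1 (0.171), 2 (0.111) or 3 (0.143). The p53 list (2 higher and 2 lower of 19, also when adjusted over the list alone; median 0.08, mean −0.07; adjusted p = 0.355) and ribosomal proteins (0 of 33 called by limma, 1 at an unadjusted p under 0.05) had no call. A control siRNA group was absent, so effects of HIF1A loss and of transfection were not separated. The lower share of calls was 31.8%, against 42.9% after quantile normalization and 42.7% centred on the tested genes.

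The polyamide against DFO asked how far a ligand directed at the hypoxia response element opposes DFO. Many HIF targets stayed near their DFO level. VEGFA went from 3374 ± 157 to 2504 ± 162 (−0.43 ± 0.19, n = 3 per group), which did not pass (adjusted p = 0.133) but did after quantile normalization (−0.49, adjusted p = 0.00103). HILPDA fell from 3197 to 1502 (−1.09 ± 0.21, adjusted p = 8.91e-04) and CA12, a carbonic anhydrase, from 327 to 91.3 (−1.85 ± 0.17). Far larger falls came in other genes: DPYD, which breaks down pyrimidines, fell from 525 to 21.1 (−4.64 ± 0.21, adjusted p = 8.65e-12), and the fibrillar collagen gene COL5A1 fell from 1027 to 195 (−2.42 ± 0.20). CXCL8 rose from 771 to 4190 (2.43 ± 0.20, adjusted p = 2.18e-08), and ASNS, the asparagine synthetase, from 796 to 2600 (1.71 ± 0.17).

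The polyamide raised 1188 genes and lowered 1191, of which 316 and 629 changed at least 2-fold. The largest falls were the chemokine receptor ACKR3 (−5.93 ± 0.63), the calcification inhibitor MGP (−5.38 ± 0.36, 211 to 6.26), IMMP2L (−4.89), DPYD, VPS13B (−4.09), the synaptic adhesion gene NLGN1 (−4.05), RBMS3 (−3.93), the glypican GPC6 (−3.91), KRT19 (−3.90) and CDKAL1 (−3.82). BEX2 rose from a clear signal (2.76 ± 0.22, 45.7 to 305), and FAM222A (2.53, 16.8 to 96.85), the secretory chaperone SCG5 (3.65) and the small GTPase RASD1 (3.53) from dim ones. SCG5 and CDKAL1 lost their calls with the ACTB ratio as a covariate (adjusted p = 0.0566 and 0.0751). ARNT, the partner of HIF-1α, was −0.99 (adjusted p = 0.00554) and lost its call without DFO array 3 (0.0536). EPAS1 was −0.59 (adjusted p = 0.0302), a call lost without DFO array 1 (0.0833), 2 (0.0876) or 3 (0.0901) or polyamide array 1 (0.136), 2 (0.0532) or 3 (0.054). EDN2 was −2.04 (adjusted p = 0.0348), lost without DFO array 1 (0.122), 2 (0.0789) or 3 (0.0828) or polyamide array 2 (0.12) or 3 (0.0836). FLT1 (−0.65, adjusted p = 0.192) and TFRC (0.15, adjusted p = 0.661) did not pass, but TFRC did after quantile normalization (0.16, adjusted p = 0.0462) and with spike-ins (0.32, adjusted p = 0.0237).

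HIF targets fell in 8 of 36, 1 rose and 27 did not pass (10 and 1 adjusted over the list alone; median −0.13, and 0.04 with spike-in scaling, where 7 fell and 4 rose). Spike-in scaling moved the median of all genes too, from 0.05 to 0.22. KISS1R (−1.22) and LOXL2 (−1.22) were among the 8. The camera call (adjusted p = 0.00947; adjusted p = 0.742 with an estimated correlation) was lost without polyamide array 1 (0.0791) or 3 (0.0677). Angiogenic factors fell in 4 of 17 and 1 rose (6 and 1 adjusted over the list alone), NRP1 at −1.81, ANGPT1 at −1.26 and EDN1 at −1.02, a call (adjusted p = 0.00965; adjusted p = 0.454 with an estimated correlation) lost without polyamide array 1 (0.0791) or 2 (0.0629). Matrix genes fell in 17 of 29 and rose in 2 (20 and 2 adjusted over the list alone; median −0.66; adjusted p = 2.8e-09, adjusted p = 0.348 with an estimated correlation), with TGFBI from 5369 to 1981, COL5A2 at −1.78 and COL4A1 at −1.62. Of the 12 glioma and astrocyte markers 5 were lower and 0 higher: GFAP (100 to 19.6), TNC (−1.37), NES (−0.67), SOX9 (−0.66) and FABP7 (−0.58). With the siRNA 4 of the 12 were called (1 higher), and with echinomycin 5 (2 higher). In the same order, the siRNA values of the 5 genes were −1.54, −0.24, 0.49, −1.61 and −1.01. Epithelial keratins went both ways with the polyamide. KRT18 (1109 to 2132) and KRT8 (0.59) were higher, and KRT19 was lower from a dim signal (18.4 to 1.22, −3.90). Iron (2 higher and 1 lower of 12, 2 and 1 adjusted over the list alone; STEAP3 −1.64; adjusted p = 0.653), glycolysis (1 and 2 of 24, 1 and 2 adjusted over the list alone, a balance that turned with spike-in scaling; adjusted p = 0.49) and interferon genes (3 and 2 of 22, 4 and 2 adjusted over the list alone; adjusted p = 0.438) had no call.

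Camera called several lists higher, though in some of them most members did not pass. The unfolded protein and integrated stress response rose in 18 of 25 and fell in 4 (18 and 5 adjusted over the list alone; median 1.00; adjusted p = 2.6e-07, adjusted p = 0.347 with an estimated correlation), with TRIB3 at 1.64 and the serine synthesis enzyme PHGDH at 1.13. NF-kB genes rose in 11 of 17 and 1 fell (14 and 1 adjusted over the list alone), with TNFAIP3 at 1.58 and SOD2 at 1.29 (adjusted p = 5.15e-07; adjusted p = 0.101 with an estimated correlation). Mitosis genes rose in 18 of 33 (20 adjusted over the list alone; median 0.60), HMMR at 1.57 and KIF20A at 1.28 (adjusted p = 1.87e-09; adjusted p = 0.413 with an estimated correlation). Cholesterol synthesis rose in 8 of 16 (10 adjusted over the list alone), IDI1 at 1.28 and FDPS at 0.83 (adjusted p = 9e-06; adjusted p = 0.347 with an estimated correlation). Immediate early genes rose in 12 of 30 and 1 fell, IER3 at −1.57 (13 and 1 adjusted over the list alone), with KLF4 at 1.89 (adjusted p = 2.77e-04; adjusted p = 0.454 with an estimated correlation). Of 19 p53 targets 5 rose (5 adjusted over the list alone), GDF15 at 2.35 and SESN2 at 1.58 (adjusted p = 0.004; adjusted p = 0.454 with an estimated correlation). Heat shock proteins rose in 2 of 11 (4 adjusted over the list alone), HSPH1 and DNAJA1 (adjusted p = 0.00463; adjusted p = 0.554 with an estimated correlation), though with probe sets that end in x or s used last HSPH1 was 0.07 (adjusted p = 0.945). Replication genes rose in 9 of 35 and fell in 2 (9 and 2 adjusted over the list alone), MCM7 at 1.11, a call (adjusted p = 0.00902; adjusted p = 0.718 with an estimated correlation) lost without polyamide array 2 (0.058). limma called 0 of 33 ribosomal protein genes, and 0 were under 0.05 without adjustment. The lower share of calls was 50.1%, and 28.1% with spike-in scaling.

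Several of the largest falls lay in very long genes, and genomic span was examined after these falls had been seen. Of the 10 largest, 7 spanned over 300 kb: the median span was 786 kb against 28.6 kb for all genes, and 12.5 kb for the 10 largest rises. DPYD spans 843 kb, NLGN1 898 kb and GPC6 1192 kb, while ACKR3, MGP and KRT19 span 45.2, 5 and 4.7 kb. Over all 14303 genes with a span, the polyamide change had a median of 0.14 under 10 kb, −0.32 at 100 to 300 kb and −0.98 over 300 kb. In the 576 longest genes, 301 fell, 2 rose and 253 were at least 2-fold lower (43.9%, against 1.21% under 10 kb). In those genes the median was 0.00 with the siRNA, 0.14 with DFO and −0.60 with echinomycin (−0.66 at 100 to 300 kb, 0.08 under 10 kb). Centred on the tested genes, these echinomycin medians were 0.395, 0.338 and 1.08, and after quantile normalization −0.16, −0.285 and 0.31. Centring shifts all genes of an array alike, so of these only quantile normalization could change the gap between classes. Genes over 300 kb lay below those under 10 kb by 0.68 with median centring and by 0.47 after quantile normalization. Across genes, which are not independent replicates, Spearman's rho of span with fold change was −0.29 for the polyamide, −0.17 for echinomycin, −0.04 for the siRNA and 0.09 for DFO. The matrix list did not rest on long genes alone: all 7 members over 100 kb fell, among them COL5A2 and COL4A1, but so did 10 of the shorter ones, and its median went from −0.66 to −0.75 after taking off the median of each span class. The ACTB 5' to 3' signal ratio, a sign of RNA integrity, was 0.403, 0.605 and 0.691 in the polyamide arrays, against 0.616 to 0.762 with DFO alone and up to 0.883 elsewhere. Without polyamide array 1 the median over 300 kb was −0.99, and on single polyamide arrays, against the mean of the DFO arrays, it was −1.005, −0.97 and −0.98. On DFO array 3, at a ratio of 0.616, it was 0.13 against the other DFO arrays.

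**Figure D2:**
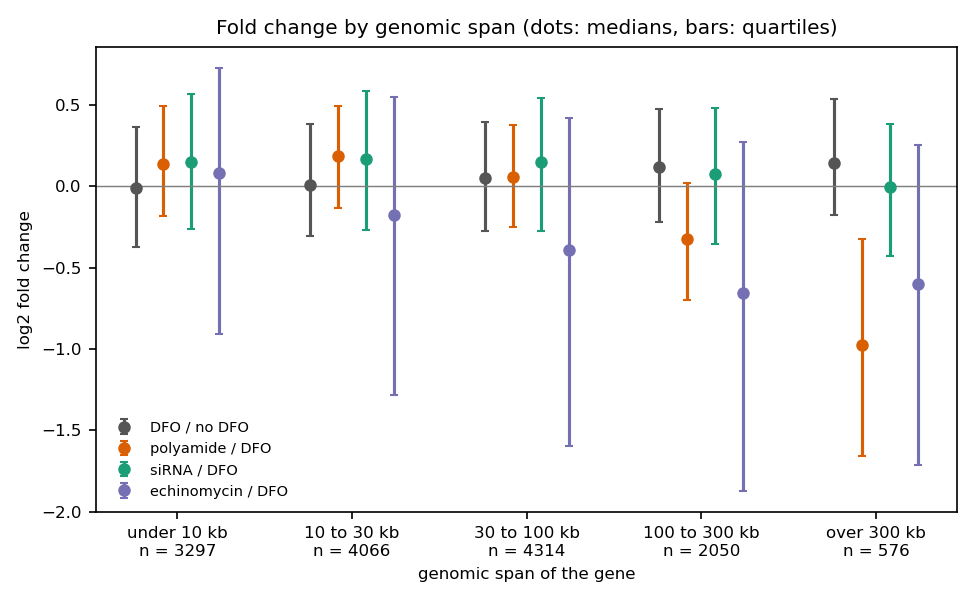
Median log2 fold change (vertical axis, bars to the quartiles) of genes in 5 classes of genomic span (horizontal axis, kb) in the 4 comparisons. The polyamide median went from 0.14 under 10 kb to −0.98 over 300 kb.

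Echinomycin against DFO asked how far a DNA-binding antibiotic opposes DFO. Its effects were wide and deep. VEGFA fell from 3374 ± 157 to 172 ± 33.0 (−4.31 ± 0.19, n = 3 per group, adjusted p = 6.77e-14). HILPDA fell from 3197 to 45.5 (−6.15 ± 0.21), the histone demethylase KDM3A from 1541 to 41.0 (−5.24 ± 0.18) and EGLN1, the oxygen sensor of HIF-1α, from 1835 to 57.6 (−5.00 ± 0.18). CDKN1A, the cell cycle inhibitor p21, fell from 655 to 19.9 (−5.38 ± 0.36) and CDK7, a kinase of the transcription machinery, from 605 to 14.9 (−5.79 ± 0.45). BIRC5 (survivin) rose from 450 ± 46.2 to 3221 ± 423 (2.84 ± 0.16, adjusted p = 3.4e-12), and the spermidine synthase SRM from 129 to 802 (2.63 ± 0.16).

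With median centring 2490 genes rose and 5485 fell, of which 1164 and 4440 changed at least 2-fold. The largest falls were GPR146 (−7.54 ± 0.33, 440 to 2.73), PNRC1 (−7.53 ± 0.42, 786 to 5.32), DEPP1 (−7.50, 1696 to 12.5), RAB20 (−7.10), the mitotic brake WEE1 (−6.74, 744 to 8.75), CSPP1 (−6.47), PRAG1 (−6.40) and BEND5 (−6.40). All of these ended below the median probe set. EYA1 (−6.84) and SIK1 (−6.62) fell too, but with probe sets that end in x or s used last their values were 0.61 and 0.54. SDC1, a syndecan (2.80, 245 to 1706), and the helicase RUVBL1 (2.79) rose from clear signals, and PAPOLA-DT, ZNF143-AS1 and the histone gene H2AC17 (3.78, 3.71 and 3.53) from dim ones. EPAS1 (−2.37 ± 0.18, adjusted p = 3.73e-10), ARNT (−2.20, adjusted p = 5.66e-08) and EDN2 (−2.23, adjusted p = 0.0056) fell, but centred on the tested genes EDN2 did not pass (−1.24, adjusted p = 0.0975). FLT1 was −0.45 (adjusted p = 0.249), and −2.59 (adjusted p = 0.0205) with probe sets that end in x or s used last. TFRC was 0.20 (adjusted p = 0.379), −0.30 after quantile normalization (adjusted p = 1.6e-04) and 1.19 centred on the tested genes (adjusted p = 7.96e-10).

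HIF targets fell in 32 of 36, and 4 did not pass (33 fell and 1 rose adjusted over the list alone; median −4.04; adjusted p = 1.13e-11, adjusted p = 0.364 with an estimated correlation); centred on the tested genes, 32 fell and 4 rose. Hydroxylases fell in 21 of 24 and 1 rose (21 and 1 adjusted over the list alone), KDM4B at −4.33 (adjusted p = 6.62e-07; adjusted p = 0.347 with an estimated correlation). Immediate early genes fell in 25 of 30 and 1 rose (25 and 2 adjusted over the list alone), DUSP1 at −4.73 and BTG1 at −4.66 (adjusted p = 7.73e-07; adjusted p = 0.348 with an estimated correlation). Stress response genes fell in 18 of 25 and rose in 3 (18 and 5 adjusted over the list alone), CEBPB at −4.66 and DDIT4 at −4.37 (adjusted p = 2.96e-04; adjusted p = 0.454 with an estimated correlation). Of 19 p53 targets, 15 fell and 1 rose (15 and 1 adjusted over the list alone), GDF15 at −4.02 and the death receptor TNFRSF10B at −3.46 (adjusted p = 0.00175; adjusted p = 0.413 with an estimated correlation). Angiogenic factors fell in 12 of 17 and 1 rose (12 and 1 adjusted over the list alone), ADM at −4.53 and EDN1 at −3.00, a call (adjusted p = 0.0332; adjusted p = 0.554 with an estimated correlation) lost without echinomycin array 1 (0.208), 2 (0.155) or 3 (0.175). Glycolysis had 3 higher and 14 lower of 24 (5 and 14 adjusted over the list alone), SLC2A3 at −4.54 and HK2 at −4.31, with no call (adjusted p = 0.0512), but with one in several other settings, among them quantile normalization (adjusted p = 3.89e-05), no filter (0.00461), x and s probe sets last (0.00853) and an offset (0.0495).

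Mitochondrial and ribosomal genes went up relative to the array median. Oxidative phosphorylation rose in 30 of 37 and fell in 2 (32 and 2 adjusted over the list alone; median 0.95; adjusted p = 2.22e-10, adjusted p = 0.454 with an estimated correlation), with ATP5MC1 at 2.22, COX6B1 at 1.41 and CYC1 at 1.27; on the deposited scale 19 rose and 4 fell. Ribosomal proteins rose in 23 of 33 (24 adjusted over the list alone; median 0.56), RPS19 from 6570 to 12380, with a call (adjusted p = 5.58e-07; adjusted p = 0.554 with an estimated correlation) that was lost after quantile normalization (adjusted p = 0.3), while on the deposited scale 0 rose and 1 fell. Replication genes split, with 17 higher and 15 lower of 35 (17 and 15 adjusted over the list alone), a balance that turned on the deposited and spike-in scales. CDC6 was at −3.30 and PCNA at −2.46, and the median (0.20) and mean (−0.30) differed in sign. Mitosis genes had 8 higher and 20 lower of 33 (8 and 21 adjusted over the list alone), KIF11 at −2.83, without a call (adjusted p = 0.475), and 17 higher and 9 lower centred on the tested genes. Heat shock proteins had 7 higher and 4 lower of 11 (7 and 4 adjusted over the list alone), HSPE1 at 1.83 and DNAJB1 at −3.79, with a median of 1.01 and a mean of −0.14. Adjusted over the list alone, the counts of the next 3 lists were the same. Matrix genes had 8 higher and 8 lower of 29 (median 0.08, mean −0.25), cholesterol genes 5 and 7 of 16, with INSIG1 from 1501 to 21.8, and metallothioneins 3 and 1 of 7 (median 0.02, mean −0.08). The cholesterol balance turned after quantile normalization and centred on the tested genes, the metallothionein one on the deposited and spike-in scales. RNA polymerase II and general factors had 11 higher and 16 lower of 30 (12 and 17 adjusted over the list alone), GTF2B at −4.81 and CCNT1 at −3.36, and turned centred on the tested genes.

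**Figure D3:**
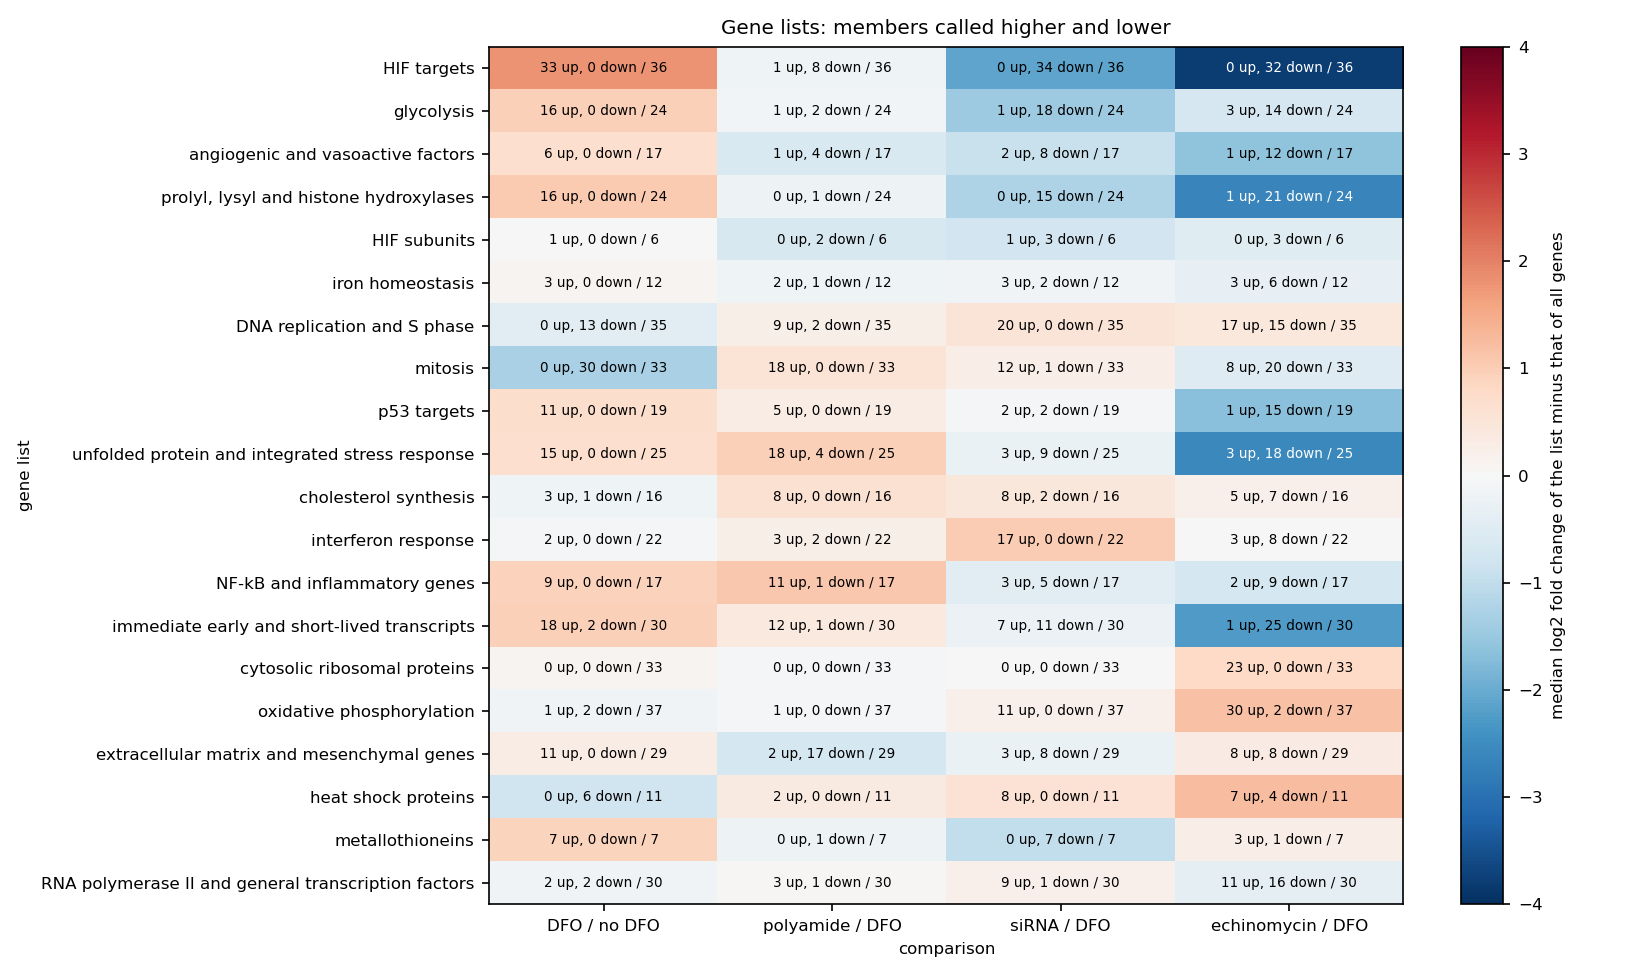
Heat map of the 20 gene lists in the 4 comparisons; colour is the list's median log2 fold change minus that of all genes, and cells give members called higher, lower and measured. With echinomycin, the ribosomal balance turned on the deposited scale, and the replication and metallothionein ones on the deposited and spike-in scales; centring on the tested genes turned the mitosis, iron and polymerase ones, and it and quantile normalization the cholesterol and interferon ones.

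The split of echinomycin calls depended on the scaling. The lower share was 68.8% with median centring, 53.2% after quantile normalization, 31.7% centred on the tested genes, 88.8% on the deposited scale and 81.9% scaled to spike-ins. The median change of all genes moved with it, at −0.23, 0.05, 0.76, −0.77 and −0.61 in the same order. For DFO the median of all genes was 0.04 with median centring, −0.20 on the deposited scale and −0.24 with spike-ins. For the polyamide it was 0.05, and 0.22 with spike-ins, and for the siRNA 0.14, and 0.02 centred on the tested genes. Falls of the depth seen for VEGFA, HILPDA and KDM3A exceed these shifts several times.

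**Figure D4:**
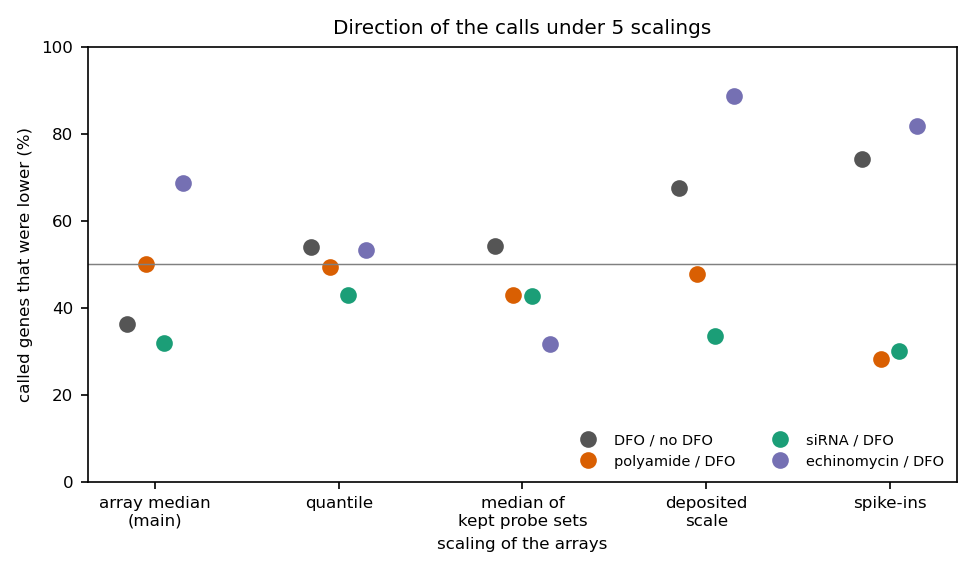
Percent of called genes that were lower (vertical axis) under 5 scalings of the arrays in the 4 comparisons. Echinomycin ran from 31.7% to 88.8%, the polyamide from 28.1% to 50.1%.

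DFO-induced genes answer the series' question most directly. DFO raised 139 genes at least 4-fold. The siRNA lowered 89 of them at least 2-fold (64.0%; 4.42% of all genes), echinomycin 121 (87.1%; 31.0% of all genes) and the polyamide 17 (12.2%; 4.39% of all genes). The median changes of the 139 were −1.83, −2.92 and −0.25. Of the 14 induced HIF targets, the siRNA and echinomycin lowered 14 each and the polyamide 2, HILPDA and KISS1R. Examples from these sets were chosen after their values were seen. The 17 genes the polyamide lowered included ACKR3 (−5.93), MEGF6 (−2.86), SEMA5B (−2.82), the natriuretic peptide NPPB (−2.57), the taurine carrier SLC6A6 (−2.32), IGFBP3 (−2.31) and the clock repressor BHLHE41 (−1.26). Of these 17, 6 spanned over 100 kb, against 16 of the other 122. The polyamide raised 11 of the 139 further at least 2-fold, among them CXCL8 (2.43), KLF4 (1.89), FOS (1.40), EGR1 (1.21) and ATF3 (1.12), while the siRNA raised 1, CXCL8, and echinomycin 0 of 139. All 3 agents lowered 15 genes, the siRNA and echinomycin 86, echinomycin alone 34, and none of them 14, such as CYP26A1. Leaving out single arrays changed the induced set itself, to between 116 and 192 genes. The share lowered was then 10.1% to 13.7% for the polyamide (13 to 23 genes), 50.4% to 68.1% for the siRNA (62 to 117) and 69.9% to 90.6% for echinomycin (86 to 155). On the deposited scale 86 genes were induced, of which the siRNA lowered 58 (67.4%), echinomycin 79 (91.9%) and the polyamide 13 (15.1%), and with spike-ins 59, 79 and 12 of 86. Centred on the tested genes, echinomycin lowered 84 of 120. Without array 3 of the cells without DFO, DFO array 3 and polyamide array 1 together, it lowered 77 of 104 and the polyamide 9.

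**Figure D5:**
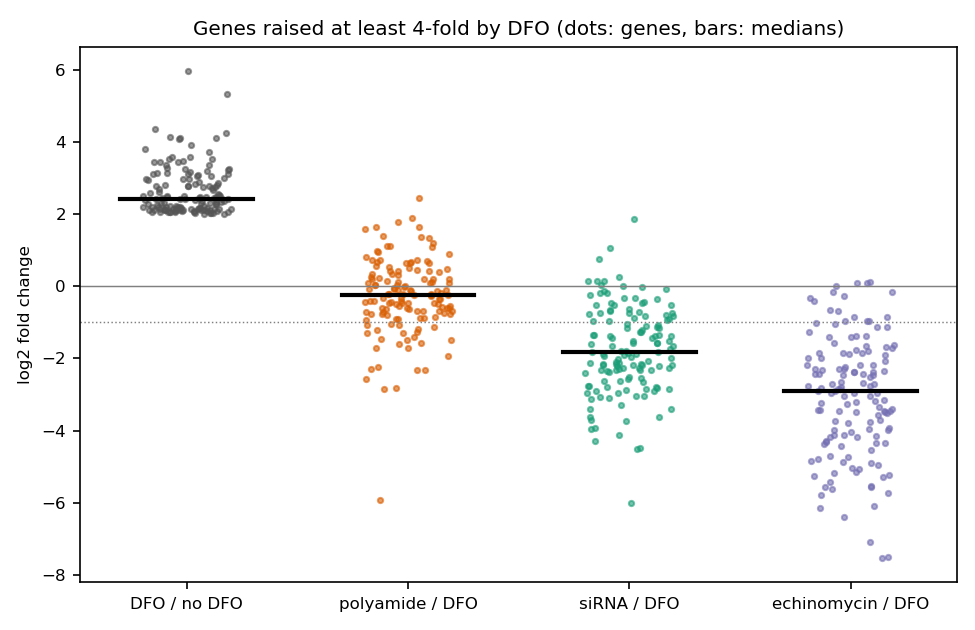
Log2 fold change (vertical axis) of the 139 genes raised at least 4-fold by DFO in the 4 comparisons; dots are genes, bars are medians and the dotted line marks −1. The medians were −0.25 with the polyamide, −1.83 with the siRNA and −2.92 with echinomycin.

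The DFO arrays enter both sides of these counts. In 50 simulations with unchanged treated groups, an average of 223 genes were induced, against 139 in the data, and 0 were lowered. Without a treatment effect almost no gene anywhere was called 2-fold lower (0.02 on average in a simulated group). The 0 was thus near certain beforehand and does not show how much the shared arrays add to the real counts. Across genes, the DFO effect correlated with the siRNA effect at r = −0.62, with echinomycin at −0.44 and with the polyamide at −0.24, against −0.26 simulated. The covariances were −0.29, −0.41 and −0.10, against −0.08 simulated (−0.084 to −0.071 over the 50 runs). Real effects widen the spread that r is divided by, so here and between treatments only covariances can be set beside the simulated values. The runs drew their spread from all 5 groups together, which makes them a rough guide. Between treatments r was 0.34 for polyamide and siRNA, 0.12 for polyamide and echinomycin and 0.29 for siRNA and echinomycin, against 0.50 simulated, with covariances of 0.17, 0.11 and 0.30 against 0.08. At least 2-fold lowered genes overlapped in 101 (polyamide and siRNA; 27.8 for independent lists), 282 (polyamide and echinomycin; 195) and 433 (siRNA and echinomycin; 196). Raised genes overlapped in 102 (19.1), 53 (25.7) and 222 (70.5). In the simulations of unchanged groups, 0 genes overlapped in any pair, in either direction; these leave out the effects, and independent lists leave out the shared arrays. The 3 DFO arrays cannot be split into sets that each keep replicates, so part of the excess may come from the shared controls.

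Direct tests set the treatments against each other, though doses, times and kinds of agent differed. VEGFA was higher with the polyamide than with the siRNA (2504 against 1125, 1.15 ± 0.19, adjusted p = 7.69e-05) and than with echinomycin (3.88 ± 0.19, adjusted p = 2.22e-13), and higher with the siRNA than with echinomycin (2.73 ± 0.19, adjusted p = 5.51e-11). EGR1, an immediate early factor, was 895 with the polyamide and 56.8 with the siRNA (3.98 ± 0.26, adjusted p = 7.01e-10). TMEM30A, a lipid flippase subunit, was 143 with the siRNA and 1600 with echinomycin (−3.48 ± 0.17, adjusted p = 2.75e-13). Of the 139 induced genes, the polyamide level was called higher than the siRNA level in 89 and lower in 2, higher than echinomycin in 114 and lower in 1, and the siRNA level was higher than echinomycin in 73 and lower in 7.

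Polyamide against siRNA had 1431 genes higher and 2660 lower. CFAP96 (6.13), S100P (4.23), RRAD (4.21) and RORA (3.87) were highest with the polyamide, and SPOCD1 (−4.48), IMMP2L (−4.46), KRT19 (−4.12), VPS13B (−4.07) and TMEM117 (−4.05) lowest. HIF targets were higher in 31 of 36 (32 adjusted over the list alone; adjusted p = 1.35e-24, adjusted p = 0.306 with an estimated correlation). Interferon genes were lower in 14 of 22 (15 adjusted over the list alone; adjusted p = 1.18e-06, adjusted p = 0.306 with an estimated correlation), and matrix genes lower in 16 of 29 and higher in 2 (17 and 2 adjusted over the list alone; adjusted p = 8.99e-04, adjusted p = 0.692 with an estimated correlation). Polyamide against echinomycin had 5568 higher and 2639 lower, PNRC1 (8.20), KLHL21 (7.36) and RAB20 (6.85) highest and MGP (−5.97), DPYD (−5.03), NEGR1 (−4.55) and GFAP (−4.48) lowest. HIF targets were higher in 31 of 36 and lower in 1 (31 and 1 adjusted over the list alone; adjusted p = 6.9e-09, adjusted p = 0.497 with an estimated correlation). The siRNA against echinomycin had 5897 higher and 1940 lower, CCDC12 (7.01), E2F3 (6.45) and KLHL21 (6.22) highest. HIF targets were higher in 21 of 36 and lower in 6 (21 and 8 adjusted over the list alone), without a call (adjusted p = 0.0812). The lower shares were 65.0%, 32.2% and 24.8%. In the first they were 51.1% centred on the tested genes and 50.3% with spike-ins. In the other 2 they were 46.2% and 45.1% after quantile normalization, 66.5% and 68.7% centred on the tested genes, 12.7% and 5.76% on the deposited scale, and 14.9% and 10.98% with spike-ins. The medians of all genes were −0.08, 0.26 and 0.33 with median centring. They moved to 0.07 (spike-ins) in the first, and ranged from −0.71 (centred on the tested genes) to 0.82 (deposited scale) in polyamide against echinomycin and from −0.79 to 0.85 in the last.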

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

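The tests of genomic span over all genes and by single array, of the echinomycin arrays and of the interferon genes were chosen only after their results were seen. Predictions for RNA degradation, dim genes and other treatments were written before those tests, but after the falls in long genes had been seen. The ACTB covariate used for RNA degradation was itself added after seeing the data. The test of other splits of the arrays was set before.

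Probe sets without a single gene symbol stand outside the comparisons of named genes, and some of them carried signal that changed. Of 5761 tested, DFO changed 306 (186 higher, 120 lower), the polyamide 302 (154 and 148), the siRNA 528 (328 and 200) and echinomycin 1693 (761 and 932). The control probe sets for 18S ribosomal RNA, which no comparison uses, read 688.8 on DFO array 3, against 101 and 89.1 on the other DFO arrays. They read 353.8 on polyamide array 1 and 275.5 on echinomycin array 2, and 57.5 to 181.5 on all remaining arrays.

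DPYD, NLGN1 and GPC6 were among many genes the polyamide lowered, and its effect grew with genomic span (rho −0.292 over 14303 genes). Degraded RNA in polyamide array 1 was argued against by the median over 300 kb without that array (−0.99) and with the ACTB ratio as a covariate (−1.03), and in the group by −0.98 on polyamide array 3, whose ratio (0.691) lies within that of the DFO arrays (0.616 to 0.762). Noise in dim genes was argued against by 99.3% of the calls over 300 kb being falls and by a median of −1.16 in the 195 bright genes of that class. A part of the DFO response was argued against by the DFO median of 0.143. A response common to all treatments was argued against by −0.003 with the siRNA, which cannot speak to one shared with echinomycin. With echinomycin the long class also lay below genes under 10 kb (−0.60 against 0.08, a difference of −0.68, or −0.47 after quantile normalization), though not below those of 100 to 300 kb (−0.66), so whether a property of both DNA-binding agents causes the trend stays open. A candidate explanation is that a ligand on DNA slows RNA polymerase over long genes, a hypothesis found and tested on the same arrays, which hold no measure of elongation.

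Echinomycin arrays had fewer bright probe sets, 11.5% to 13.0% above a signal of 100 against 19.0% to 24.8% on the others (14.74% to 15.55% against 16.87% to 21.95% after median centring). Uniformly dimmer arrays were argued against by ribosomal protein genes, whose median change on the deposited scale was 0.03 (quartiles −0.11 and 0.17) where all genes moved by −0.77, and by oxidative phosphorylation at 0.42. Weaker hybridization was argued against by the spike-ins, which differed by −0.159. At least 2256 genes were 2-fold or more lower under each of 5 scalings, with up to 5920. A count of lower genes cannot decide whether a net loss rests on the choice of scaling. Centred on the tested genes, 6917 genes were higher and 3212 lower, with a median of 0.76 over all genes. A general loss of short-lived RNA may lie behind the fewer bright probe sets. DUSP1, BTG1 and the rest of the immediate early list had a median of −2.50. However, RNA per cell was not measured, and the spike-ins, added at hybridization, do not show such a loss.

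Interferon genes such as IFI27, RSAD2 and IFIT3 rose with the siRNA. Release of a repression set by DFO was argued against by 17 of the 22 being higher than in cells without DFO as well (median 1.41), while the DFO median was −0.04. Blood cells in the siRNA wells were argued against by the leukocyte markers: of the 3 above the filter limma called 0 higher, 0 were higher at an unadjusted p under 0.05, and the brightest value of the 6 on any array was 77.9. A response to the transfected RNA and an effect of HIF1A loss both stay open and untested, since no group received a control siRNA.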

How the results depend on the processing

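The deposited scale, the spike-in scaling, the ACTB covariate and the set without doubted arrays were chosen only after results were seen; the others were planned. For the 11 main results, 241 values kept their direction and stayed within 1.5 times of the reported one or kept their call, and 37 moved. Of the single-gene results, 9344 values kept direction and call, 200 lost the call, 137 gained one and 13 reversed. For lists, 1820 kept both, 71 lost the call (46 with an estimated correlation), 27 gained one and 2 reversed. HIF1A with the siRNA stayed between −3.00 and −2.76 when 1 array was left out.

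Counts of changed genes are given in the order DFO, polyamide, siRNA, echinomycin, polyamide against siRNA, polyamide against echinomycin, siRNA against echinomycin. Testing all probe sets gave 3161, 3731, 6183, 14051, 6928, 14543 and 13633, since it counts probe sets and not genes. Quantile normalization gave 3644 for DFO and 3657 for the polyamide, centring on the tested genes 3508 and 3737, and spike-ins 3511 and 3646; the cause was not tested. Array weights gave 5950, 4944, 6357 and 6312 (DFO, polyamide, siRNA, polyamide against siRNA), and 26 induced genes lowered by the polyamide. With only the groups compared in the fit, 4255 passed for the polyamide, 6213 for the siRNA and 1781 for DFO. The main fit shares 1 spread per gene over groups that replicated unequally. The lowest replicate r was 0.934 without DFO and 0.935 with echinomycin, against 0.960 (DFO), 0.962 (siRNA) and 0.954 (polyamide). Whether this caused the differences was not tested. Stricter thresholds gave fewer by construction: at least 2-fold 917, 945, 1500 and 1897 (polyamide against siRNA), and adjusted p under 0.01 1218, 1345 and 2531.

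Induced genes lowered numbered 72 (polyamide), 315 (siRNA) and 554 (echinomycin) when a 2-fold rise counted as induced. On the deposited scale 58 (siRNA) and 79 (echinomycin) were lowered, and with spike-ins 59 and 79, each of 86 induced. Without the doubted arrays (array 3 without DFO, DFO 3 and polyamide 1) the polyamide lowered 9 and echinomycin 77 of 104 induced.

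Leaving out single arrays gave 1398 to 3121 genes for DFO, 1636 to 1950 (polyamide), 2878 to 3171 (siRNA), 7404 to 7679 (echinomycin), 3211 to 3451, 7663 to 7876 and 7212 to 7480 (direct comparisons), and 13 to 23, 62 to 117 and 86 to 155 induced genes lowered by polyamide, siRNA and echinomycin, of 116 to 192 induced. The lowest DFO count was without DFO 3 and the highest without array 3 of the cells without DFO. In all, 8 lists and 29 single-gene results lost their call when some array was left out.

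Reversals came from few settings; the cause was not tested. TFRC with echinomycin was −0.30 after quantile normalization (and 1.19 centred on the tested genes), and in polyamide against echinomycin 0.46, 0.51 and 0.49 with quantile, deposited and spike-in scales (and −1.02 centred on the tested genes). HIF1A, centred on the tested genes, was 0.70 with echinomycin and −0.70 in polyamide against echinomycin. With x and s probe sets last, EYA1 (0.61), SIK1 (0.54), IFI44 (0.41) and NFKBIA (0.87) turned with echinomycin, SC5D (−0.10) and NFKBIA (−0.78) with DFO, and FLT1 (2.21) in polyamide against echinomycin. The ribosomal list turned to −0.10 with DFO under array weights, and fry called the cholesterol list lower with echinomycin (adjusted p = 0.00182), though its median lay 0.20 above that of all genes and camera pointed up without a call.

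Replicate numbers did not pair the arrays (residual correlations −0.039 to 0.040). With the number as a block, 2023, 2322, 3781, 7974, 4076, 8196 and 7806 genes passed and 17, 88 and 121 induced genes were lowered, HIF1A was −2.85, and the tested calls stayed as they were. Each of the 7 comparisons has 10 splits of its 6 arrays, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes. All other splits mix arrays of both groups, which puts the group difference into the spread and leaves few calls. Their low counts do not show what unchanged groups would give. The highest of the others was 0 (DFO, real 2071), 1 (polyamide, 2379), 0 (siRNA, 3850), 1 (echinomycin, 7975), 0 (polyamide against siRNA, 4091), 1 (polyamide against echinomycin, 8207) and 1 (siRNA against echinomycin, 7837). Values below the probe median of 13.3 limit folds such as those of GPR146, ACKR3 and KRT19.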

Other observations

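The test of genomic span over all genes, set here beside the response to hypoxia, was chosen only after its result was seen.

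DFO raised HILPDA, IGFBP3 and VEGFA and lowered CDC20 and CCNB1. The siRNA moved all of these back towards their level without DFO: IGFBP3 was 104 without DFO, 3616 with it and 188 after the siRNA, and CDC20 was 1329, 166 and 365. The polyamide raised CCNB1 too (388 to 823), but it lowered 17 of 139 induced genes at least 2-fold with a call, against 89 for the siRNA. The polyamide change of the 139 had a median of −0.25 (quartiles −0.76 and 0.36), and genes without a call may still have fallen. EGR1, ATF3 and CXCL8, which DFO raised, rose further with the polyamide, and ASNS and TRIB3 of the integrated stress response rose too. MT3 and the other metallothioneins, raised by DFO in 7 of 7, fell in 7 of 7 with the siRNA.

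The polyamide lowered 17 of the 139 DFO-induced genes at least 2-fold (12.2%, against 4.39% of all genes), among them HILPDA and IGFBP3. Of the 576 genes over 300 kb, such as DPYD, it lowered 43.9% by that much, against 1.21% under 10 kb. HIF targets had a median of −0.13 (−0.30 after taking off the median of each span class, and 0.04 before it with spike-in scaling). The median of all genes was 0.05, and 0.22 with spike-ins, so the list lay below it under both. The span values go with an effect on long genes. For the induced genes, the DFO arrays enter both the rise and the fall. The DFO and polyamide effects had a covariance of −0.10, against −0.08 in simulated unchanged groups (−0.084 to −0.071 over 50 runs). Their r was −0.24 against −0.26, but real effects widen the spread that r is divided by, so the r values cannot be compared. In those runs 0 induced genes were lowered, so the shared arrays without any treatment effect do not account for the 17. Whether there is an effect on the induced genes beyond that on other genes, apart from the shared arrays, was not settled. Binding of the polyamide to DNA was not measured, so direct targets and the weight of either effect are open.

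KLK3 and the other prostate markers did not follow any treatment together: FKBP5 was 57.7 with DFO alone, 124 with the siRNA and 116 with the polyamide, while KLK3 was 75.7, 79.0 and 72.9. HOXB13 was dim, at 7.05 with DFO alone and between 19.6 and 23.7 in the other groups. GFAP was 163 without DFO, 100 with DFO alone, 41.3 with the siRNA, 19.6 with the polyamide and 305 with echinomycin.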
